A study of Mus musculus with 4 samples.

How the data were processed

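Mouse EB5 ES cells with a Hoxb6-Venus reporter were grown for 6 days on OP9 feeder cells, stained for Flk-1 and sorted, per the labels' protocols. RNA was isolated with a Qiagen micro-elute kit and labelled with Cy3 by an Agilent low-input amplification kit, per the labels' protocols. The 4 arrays comprised 2 of the Flk-1+ Venus-positive and 2 of the Flk-1+ Venus-negative fraction. All were on 1 slide with 1 scan, and the row on the slide coincided with the replicate number. Whether the column on the slide went with the fraction was not examined.

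Each deposited scanner table holds intensity values per spot from Agilent Feature Extraction 10.10.1.1, per the file headers. The processed signal used here is background-subtracted and spatially detrended within each array, with no scaling between arrays, per the file headers. The value table deposited by the authors holds intensity values on a linear scale. Comparison with the scanner values showed them to be the processed signal times 1 constant per array (2.15, 2.44, 1.98 and 2.11), without centring of genes; how the constants were set is not stated. Its column medians were 41.0 and 42.3 for the Venus-negative and 41.0 and 38.1 for the Venus-positive arrays.

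Of 62976 spots, 59305 were not controls and represented 55681 probes. Control spots were left out, as were 187 and 152 outlier spots on the Venus-negative and 196 and 189 on the Venus-positive arrays. The log2 processed signal was centred on each array's 75th percentile, which lay at a signal of 396 and 347 for Venus-negative and 429 and 398 for Venus-positive arrays. Spots of a probe were averaged. Probes well above background on both arrays of at least 1 group were kept (27899 probes, of which 2 were left out for outlier spots). The share of spots well above background sets how small a transcript level could be followed.

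Array accessions without version were matched to gene symbols through a RefSeq table of assembly GRCm38.p6. Of 37881 distinct accessions, 21465 matched 1 symbol and 0 matched several; among RefSeq transcript accessions 21451 of 21887 matched. In all, 27235 probes had 1 symbol and 28446 had none and stayed unnamed. A gene was represented by its probe with the highest mean signal, leaving 23547 features: 13925 genes and 9622 unnamed probes. For named genes with several probes, those that differed most from the representing probe are given, but not every other probe. Coordinates of unnamed probes are those of the array design, in build mm9.

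The fractions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Venus-positive minus Venus-negative), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05; the package data.table (version 1.17.8) held the data. The fit had 2 residual and 1.8 prior degrees of freedom. SE is the moderated standard error. For a gene well above background on neither array of a group, the fold is given as a lower bound: the mean of the bright group against, for each dim array, the higher of the gene's own signal and the lowest signal among probes well above background. A gene well above background on 1 of the 2 arrays of a group keeps its measured value, with that count beside it.

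The test, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The 27 lists were Hox paralog groups 1 to 4, 5 to 9 and 10 to 13; primitive streak and nascent mesoderm; lateral plate and extraembryonic, cardiac, paraxial and intermediate mesoderm; endothelial, arterial, and venous and lymphatic genes; early hematopoietic and erythroid genes; smooth muscle and pericyte genes; OP9 stromal, fibroblast and adipocyte genes; pluripotent ES cell, endoderm, and neural and neural crest genes; G1/S and G2/M genes; dissociation stress genes; BMP and TGF-beta, Notch, Wnt, and retinoic acid and caudal genes; extracellular matrix and epithelial-mesenchymal transition genes; and glycolysis and hypoxia genes. They hold 466 distinct genes, of which 409 were tested; for 3 (Hbb-b1, Ahsp and Hspa1b) no probe matched the symbol. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 27 lists, with an estimated correlation and limma's fry as alternatives. With an estimated correlation camera rests on only 2 residual degrees of freedom, so few lists could pass. A call lost there does not by itself show correlated members. Counts over a list are given over all features and adjusted over the list alone.

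The rule for named genes took Hoxb6 and Kdr; any measured Hox gene; the 10 largest increases and 10 largest decreases past the threshold, on genes well above background on all 4 arrays with no overlap between groups, passing over clone and predicted-gene names; up to 5 bounds per direction; and the members with the largest change of each list, up to 4 where the list passed and up to 2 otherwise. Genes outside the rule are marked as named after the data were seen.

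Alternatives were model-based background correction (normexp, offset 50), quantile normalization, median centring, no filter and a stricter filter on dim probes, other probe rules, a signal-dependent robust variance prior, the replicate number as a block, the deposited value table, other thresholds, and leaving out each array in turn. Normexp used the median spot signal, since the mean spot signal is not among the deposited columns. Its offset of 50 exceeded the median processed signal of every array (17.3 to 20.7), so it shrinks changes of dim genes by construction. Smaller normexp changes of such genes therefore do not by themselves test a bound or a call. Slide and scan were not fitted as blocks, since there was 1 of each. The procedure was tested on simulated data with 23547 features, 200 changed genes and 20 simulations of this comparison. It called 9.95% of genes changed by a log2 value of 1 and 94.7% of those changed by 3; 119 of 2257 calls were false. A list shifted by 1 was called in 20 of 20 simulations. Other lists, leaving out the arterial, venous and lymphatic, and endoderm lists, were called 5 times. Gene variances were the moderated estimates from these arrays, so the recovery and false-call counts hold only for that spread. Genes were drawn independently of each other, so these list counts do not cover lists whose members vary together. Plots were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.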

Results

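Gene expression was measured in 2 sorted fractions of differentiating mouse embryonic stem (ES) cells. The cells were EB5 ES cells carrying a Venus fluorescent reporter of Hoxb6, a homeobox gene of the trunk mesoderm, and had been cultured for 6 days on OP9 stromal feeder cells. Cells stained for Flk-1, the VEGF receptor encoded by Kdr that marks mesoderm and its vascular and blood derivatives, were separated into a Venus-positive and a Venus-negative fraction. Total RNA of each fraction was hybridised to 2 single-colour Agilent arrays, 4 arrays in all, each with 62976 spots. Between 50.7% and 53.0% of the spots that were not controls lay well above background on each array, and 0 spots were saturated. The small number of arrays limits the precision of every value. Whether the replicates came from separate differentiation cultures is not stated, so p-values measure only the spread between these samples, which may be technical.

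Arrays of the same fraction resembled each other more closely than arrays of different fractions. Across genes and unnamed probes, which are not independent replicates, Pearson's r was 0.991 between the 2 Venus-negative arrays and 0.993 between the 2 Venus-positive arrays. Between fractions it ranged from 0.977 to 0.984. The median absolute log2 difference was 0.178 between the Venus-negative and 0.158 between the Venus-positive arrays, against 0.242 to 0.276 between arrays of different fractions.

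The design poses a single question: which transcripts differ between Flk-1+ cells with and without Hoxb6 reporter activity. Among the largest differences were lower levels in the Venus-positive cells of genes active in the primitive streak, the site where mesoderm forms. Gsc, a streak homeobox gene, was 40.3-fold lower than in the Venus-negative cells (log2 change -5.33 ± 0.37 SE), Mixl1 35.4-fold lower (-5.15 ± 0.42) and Eomes 30.0-fold lower (-4.91 ± 0.30). Endothelial genes were higher in the Venus-positive cells by a smaller factor, among them Sox18, a transcription factor of blood and lymph vessels (2.89-fold, log2 change 1.53 ± 0.11), and Mmrn2, an endothelial matrix protein (2.91-fold, 1.54 ± 0.12). In all, 137 genes were higher and 257 lower in Venus-positive cells at a Benjamini-Hochberg adjusted p under 0.05 in limma, out of 13925 genes tested. Decreases were also deeper: with genes dim in 1 fraction taken at their bound, 48 of the lower genes and 1 of the higher genes changed by at least 3 on the log2 scale. The higher gene was Pou4f2, a homeobox transcription factor known from sensory neurons and named after the data were seen (3.23 ± 0.22, adjusted p = 0.0349), which was well above background on 1 of the 2 Venus-negative arrays.

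With dim genes at their bound, 235 of the lower genes fell and 117 of the higher genes rose at least 2-fold. Among 9622 probes without a gene symbol, 46 were higher and 63 lower. With each array centred on its median in place of its 75th percentile, 259 genes were higher and 296 lower, so that 53.3% of the called genes were lower against 65.2% in the reported fit. The adjusted p-values lay close to the threshold, at 0.0246 or above for the genes named here: 0 genes passed in limma without Venus-negative replicate 1, Venus-negative replicate 2, Venus-positive replicate 1 or Venus-positive replicate 2, and 0 when dim probes were kept in the test. At an unadjusted p under 0.05, 1968 genes were higher and 1658 lower with all 4 arrays, 1106 to 1514 higher and 1111 to 1333 lower without 1 array, and 1736 higher and 1783 lower with dim probes kept. Model-based background correction (normexp), which compresses low signals, moved the log2 change of Gsc to -3.63 and that of Mixl1 to -3.58 and called 491 genes higher and 538 lower.

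**Figure D1:**
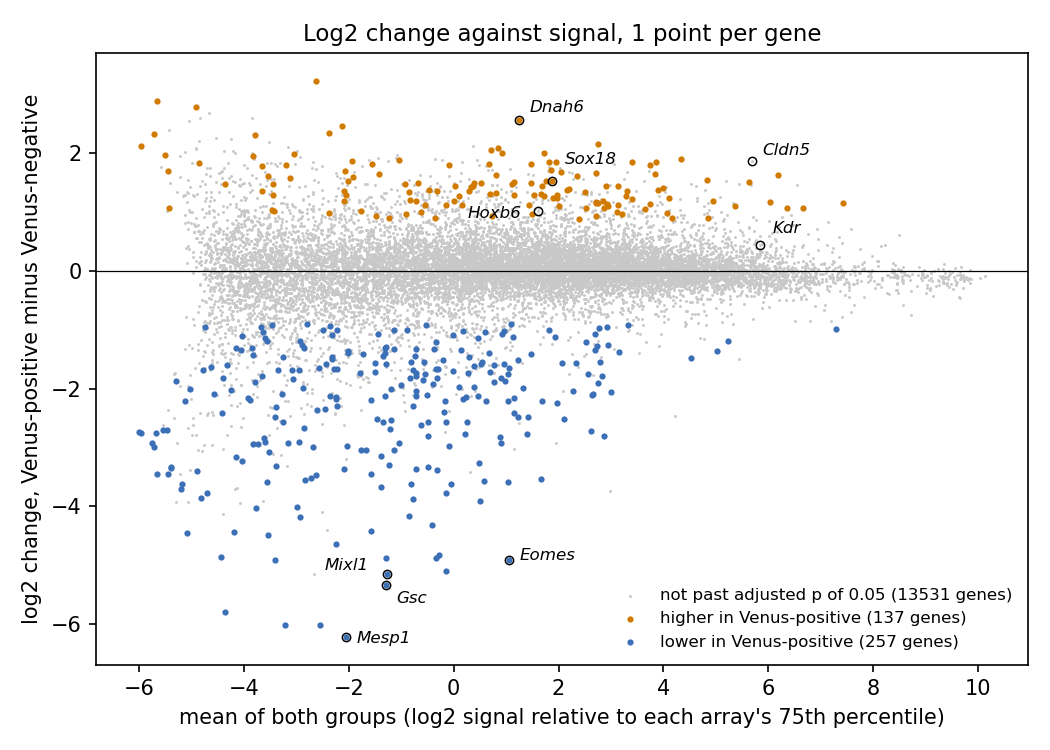
Log2 change of every tested gene (Venus-positive minus Venus-negative, vertical axis) against its mean normalised log2 signal over both groups (horizontal axis), 1 point per gene, with genes dim in 1 fraction drawn at their measured value; coloured points are the 137 higher and 257 lower genes at an adjusted p under 0.05, and circles mark 9 named genes. The decreases of streak genes (Gsc at -5.33, Mixl1 at -5.15) are larger than the increases of the circled endothelial genes, such as Cldn5 at 1.86.

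The sorting marker Hoxb6 was 2.02-fold higher in the Venus-positive cells. Its normalised log2 signal was 1.10 ± 0.17 (SD, n = 2) in Venus-negative and 2.12 ± 0.17 (SD, n = 2) in Venus-positive cells. The log2 change of 1.01 ± 0.16 SE exceeded the spread of the replicates, but its limma adjusted p of 0.0716 missed the threshold. It passed with a signal-dependent variance prior (adjusted p = 0.0290) and with model-based background correction (adjusted p = 0.0338). Kdr, the gene of the receptor on which both fractions were selected, was bright in both, at 5.63 ± 0.12 in Venus-negative and 6.07 ± 0.02 in Venus-positive cells (SD). Its log2 change was 0.44 ± 0.11 SE, a factor of 1.35, with an adjusted p of 0.138. This passed only with the signal-dependent variance prior (adjusted p = 0.0478). A second Kdr probe gave 0.25 ± 0.10 (limma adjusted p = 0.243).

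**Figure D2:**
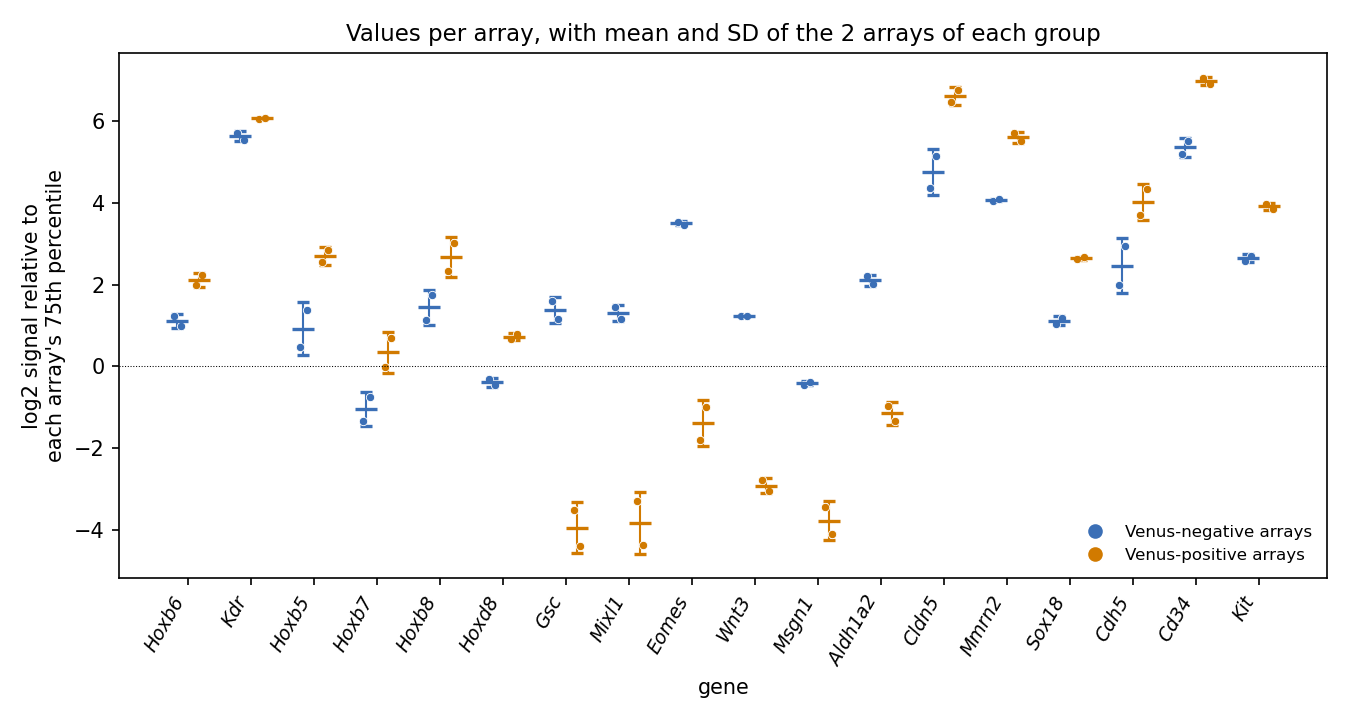
Normalised log2 signal (vertical axis, relative to each array's 75th percentile) of 18 genes (horizontal axis) on the 2 Venus-negative and 2 Venus-positive arrays; points are arrays, and horizontal bars with whiskers are the mean and SD of the 2 arrays of a group. Hoxb6 lies at a mean of 1.10 in Venus-negative and 2.12 in Venus-positive cells, Gsc at 1.38 and -3.96, and Cldn5 at 4.76 and 6.62.

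The primitive streak and nascent mesoderm genes formed the most strongly shifted list. Of 13 measured members, 9 fell past the threshold, 12 when adjusted over the list alone, and 13 of 13 had a negative log2 change, with a median of -4.48, or -4.16 with Fgf5 set at its bound. Mesp1, a regulator of the earliest cardiovascular mesoderm, was lower with an adjusted p of 0.0342. Its measured log2 change of -6.22 ± 0.38 SE rests on signals well above background on only 1 of the 2 Venus-positive arrays, and was -3.78 with normexp. Wnt3, a Wnt ligand needed to form the streak, fell 17.8-fold (log2 change -4.16 ± 0.13). Fgf5 was not well above background in the Venus-positive cells and had a log2 signal there at least 3.81 lower (adjusted p = 0.0342), against a log2 change of -1.88 with normexp. Against this, the streak gene T had a log2 change of only -0.73 ± 0.25 (adjusted p = 0.202), a value given after the data were seen. Camera placed the list below other genes with an adjusted p of 8.27e-13 at a preset correlation; the adjusted p was 0.402 with an estimated correlation.

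Besides Gsc, Mixl1 and Eomes, the 10 largest decreases among genes measured on all 4 arrays included Cfc1, a co-receptor of the signalling protein Nodal, which fell 34.2-fold (log2 change -5.10 ± 0.23), and Lefty2, a Nodal antagonist, which fell 28.4-fold (-4.83 ± 0.33). Tdgf1, the related co-receptor Cripto, fell by 4.89 ± 0.14 on the probe that represents it. A second probe of this gene gave -4.67 ± 0.22 (adjusted p = 0.0304), whereas another gave -0.83 ± 0.38 (adjusted p = 0.289). The remaining large decreases were Six2, a transcription factor of kidney progenitors (-4.88 ± 0.13), Lhx1, a homeobox gene of streak and kidney precursors (-4.64 ± 0.14), Phox2a, known from autonomic neurons (-4.42 ± 0.47), and Ptgds, a prostaglandin D synthase (-4.32 ± 0.17). Adjusted p-values of the 10 genes lay between 0.0246 and 0.0469. With normexp the log2 change of Lhx1 moved to -2.69 and that of Phox2a to -2.99. Genes below the background criterion in Venus-positive cells gave lower bounds: Optc, a small matrix proteoglycan, was at least 47.3-fold lower, Myl7, the atrial myosin light chain, at least 29.8-fold, Adcyap1r1, a neuropeptide receptor, at least 17.9-fold, and S1pr5, a sphingosine phosphate receptor, at least 15.3-fold. These bounds hold for the processed signal. With normexp the 4 genes still passed but lay below them, with log2 changes of -2.93 (Optc), -2.45 (Myl7), -2.18 (Adcyap1r1) and -1.65 (S1pr5). The offset added by normexp keeps changes to a dim signal small, so this does not test the bounds.

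Camera also called the Wnt list (adjusted p = 2.44e-05) and the paraxial mesoderm list (0.00200) lower at the preset correlation. With an estimated correlation the adjusted p was 0.521 and 0.402. In fry the Wnt list did not pass (0.0726), and with dim probes kept the paraxial list did not (0.176). Of 20 measured Wnt signalling genes, 4 fell (10 adjusted over the list alone), with a median log2 change of -1.16. Beside Wnt3, the secreted Wnt antagonist Frzb fell 7.98-fold (adjusted p = 0.0375), and Rspo3 and Wnt5a, named after the data were seen, had log2 changes of -1.55 and -1.51. Wnt8a (-2.29 ± 0.37, adjusted p = 0.0775, measured on 1 of 2 Venus-positive arrays) and Dkk1 (-1.73 ± 0.36, adjusted p = 0.110) did not pass. Of 14 paraxial mesoderm and somite genes, 3 fell (6 adjusted over the list alone), with a median of -0.61: Dll3, a somite Notch ligand, with a log2 change of -3.91 ± 0.25, Msgn1, a regulator of presomitic mesoderm, with -3.37 ± 0.26, and Pdgfra, a growth factor receptor named after the data were seen, with -1.93 ± 0.21. Tbx6, which acts with Msgn1, missed the threshold at -2.92 ± 0.43 (adjusted p = 0.0687). With normexp Msgn1 stood at -1.93 and Tbx6 at -2.72, and Tbx6 then passed in limma (adjusted p = 0.0249).

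Camera called the cardiac (adjusted p = 0.000353), lateral plate (0.00230), intermediate mesoderm (0.00770) and endoderm (0.00304) lists lower at the preset correlation. With an estimated correlation the adjusted p was 0.402, 0.459, 0.402 and 0.402. The lateral plate and endoderm lists did not pass in fry (0.122 and 0.0581), and with dim probes kept the lateral plate (0.0523), intermediate (0.109) and endoderm (0.141) lists did not. In the cardiac list, Myl7 alone fell among 16 measured genes (7 adjusted over the list alone), and 13 of the 16 log2 changes were negative, with a median of -1.20 (-0.78 without Venus-positive replicate 2). Myh6, the alpha cardiac myosin heavy chain, had a log2 change of -2.62 ± 0.57 (adjusted p = 0.113) and Smarcd3, a chromatin remodelling subunit of cardiac mesoderm, -1.79 ± 0.24 (adjusted p = 0.0617). Of 18 lateral plate and extraembryonic mesoderm genes, 1 fell (4 adjusted over the list alone), with a median of -0.71 (-0.44 without Venus-positive replicate 2). This was Gata4, a heart and endoderm transcription factor, which was 12.3-fold lower (log2 change -3.62 ± 0.32). Of 9 intermediate mesoderm genes, 3 fell over all genes tested: Six2 and Lhx1, given above, and Sall1, named after the data were seen (adjusted p = 0.0465). Adjusted over the list alone, 4 were lower and 2 higher, the latter being Gata3 (1.19 ± 0.31) and Wt1 (1.55 ± 0.44), neither of which passed over all genes (adjusted p = 0.143 and 0.157). The list's median was -0.53. Of 14 endoderm genes, 2 fell, the epithelial keratins Krt8 (-2.77 ± 0.24) and Krt19 (-2.16 ± 0.19), and the median was -0.57. Sox17, shared with the endothelial list, went the other way at 1.35 ± 0.24 (adjusted p = 0.0872). Adjusted over the endoderm list alone, 6 genes were lower and 1 higher.

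Endothelial genes were higher as a list in camera (adjusted p = 8.27e-13 at the preset correlation, and adjusted p = 0.402 with an estimated correlation). Of 26 measured members, 6 were higher over all genes, and 23 were higher and 1 lower when adjusted over the list alone; 25 of 26 log2 changes were positive, with a median of 1.20. Cldn5, a tight junction protein of endothelium, was 3.63-fold higher and Cdh5, VE-cadherin, 2.96-fold, but their replicates spread more (log2 change 1.86 ± 0.32 and 1.56 ± 0.42 SE, adjusted p = 0.0839 and 0.148). The exception in sign was Etv2, a transcription factor that starts the endothelial and blood programme, at -1.50 ± 0.26 (adjusted p = 0.0850, named after the data were seen). Of 12 arterial genes, Acvrl1, a TGF-beta family receptor, rose 2.87-fold (log2 change 1.52 ± 0.11), Cxcr4, a chemokine receptor, stood at -2.01 ± 0.37 (adjusted p = 0.0895), and the list did not pass (median 0.03, adjusted p = 0.467, with 2 higher and 2 lower adjusted over the list alone). The arterial median was 0.21 without Venus-negative replicate 1, 0.06 without Venus-negative replicate 2, -0.02 without Venus-positive replicate 1 and 0.40 without Venus-positive replicate 2. The 9 venous and lymphatic genes had a median of 0.61 with an adjusted p of 0.0783, which passed with normexp (0.0234, at a smaller median of 0.27), with dim probes kept (0.00656) and in fry (0.0225). Without Venus-negative replicate 1 the median was 0.31 (adjusted p = 0.101). Of these, 0 genes were called over all genes in limma (4 higher adjusted over the list alone and 4 at an unadjusted p under 0.05), the largest value being that of Nr2f2, a regulator of venous identity (1.72 ± 0.34, adjusted p = 0.103).

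Camera called the Hox genes of paralog groups 5 to 9 (adjusted p = 0.0107) and 10 to 13 (0.00559) higher in Venus-positive cells at the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.402 for both) or in fry (0.174 and 0.0520). The call of groups 10 to 13 was also lost with normexp (0.0940, at a median of 0.27) and with dim probes kept (0.176, at a median of -0.07). Groups 5 to 9, which include the reporter gene Hoxb6 and are therefore not independent of the sort, had 14 measured members, 12 with a positive log2 change and a median of 0.35. Without Venus-negative replicate 2 the median was 0.16 and the call was lost (adjusted p = 0.119). The median was 0.53 without Venus-negative replicate 1, 0.19 without Venus-positive replicate 1 and 0.53 without Venus-positive replicate 2. Hoxd8 passed over all genes (2.17-fold, log2 change 1.12 ± 0.12), and 3 members were higher when adjusted over the list alone. The neighbours of Hoxb6 stood at 1.77 ± 0.36 SE (Hoxb5), 1.39 ± 0.35 (Hoxb7) and 1.24 ± 0.35 (Hoxb8), with adjusted p-values of 0.105, 0.136 and 0.154. Of groups 10 to 13, 5 members were measured. Hoxa10, Hoxc10 and Hoxa11 entered the test through the Venus-positive arrays alone, being well above background on 0, 0 and 1 of the 2 Venus-negative arrays. Hoxa10, dim in the Venus-negative cells, was at least 1.81-fold higher (adjusted p = 0.0349) and was the only member called; 3 were higher adjusted over the list alone. With normexp the log2 change of Hoxa10 was 0.27, below that bound, and did not pass (adjusted p = 0.287). The normexp offset is large against so dim a signal, so a smaller change was built in. Hoxc10 was at least 2.43-fold higher (adjusted p = 0.0682, log2 change 0.31 with normexp), and Hoxd10 had a log2 change of 0.85 ± 0.11 (adjusted p = 0.0570), or 0.38 with normexp. Hoxa11 stood at 0.77 ± 0.96 and turned negative without Venus-negative replicate 1 (-0.20) or Venus-positive replicate 2 (-0.11). The list's median was 0.85, and 1.74 without Venus-negative replicate 2 and 1.53 without Venus-positive replicate 1. Groups 1 to 4, with 12 measured members, had a median of -0.06 (adjusted p = 0.749), which was -0.01 without Venus-negative replicate 1, -0.24 without Venus-negative replicate 2 and 0.02 without Venus-positive replicate 1, and was under 0.01 in size without Venus-positive replicate 2. Hoxb1 stood at -1.56 ± 0.50 (adjusted p = 0.185). Of that list 0 genes passed in limma over all genes; adjusted over the list alone, 1 was higher and 1 lower, and at an unadjusted p under 0.05, 2 were higher and 2 lower.

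Camera called the mitotic genes higher (adjusted p = 2.68e-06) and the glycolytic genes lower (0.00641) as lists at the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.538 and 0.547) or in fry (0.164 and 0.196). In limma 0 members of either passed over all genes or adjusted over the list alone (at an unadjusted p under 0.05, 11 mitotic genes were higher, and 1 glycolytic gene was higher and 6 lower). All 19 measured G2/M and mitosis genes had a positive log2 change, with a median of 0.65 (0.90 without Venus-negative replicate 1 and 0.40 without Venus-negative replicate 2), led by the spindle protein Nusap1 (1.35 ± 0.27 SE, adjusted p = 0.102), Ube2c (0.95 ± 0.26, adjusted p = 0.151), Cdk1 (0.91 ± 0.22, adjusted p = 0.125) and Cenpe (0.91 ± 0.19, adjusted p = 0.110). Between the 2 Venus-negative arrays the same list differed by a median of 0.49, with replicate 2 the lower. The 19 genes of G1/S and DNA replication had a median of -0.13 and an adjusted p of 0.127 (0.0406 without Venus-negative replicate 2); 0 were called in limma over all genes or adjusted over the list alone, and 1 was higher and 3 lower at an unadjusted p under 0.05. Of 20 glycolysis and hypoxia genes, 17 had a negative log2 change, with a median of -0.37. Aldoc stood at -1.33 ± 0.49, Pfkp at -0.60 ± 0.22 and Pgk1 at -0.58 ± 0.18 (adjusted p = 0.229, 0.224 and 0.178), and Pdk1 at 0.58 ± 0.24 (adjusted p = 0.256). The list's call was also lost without Venus-negative replicate 2 (adjusted p = 0.0614) and with dim probes kept (0.141).

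**Figure D3:**
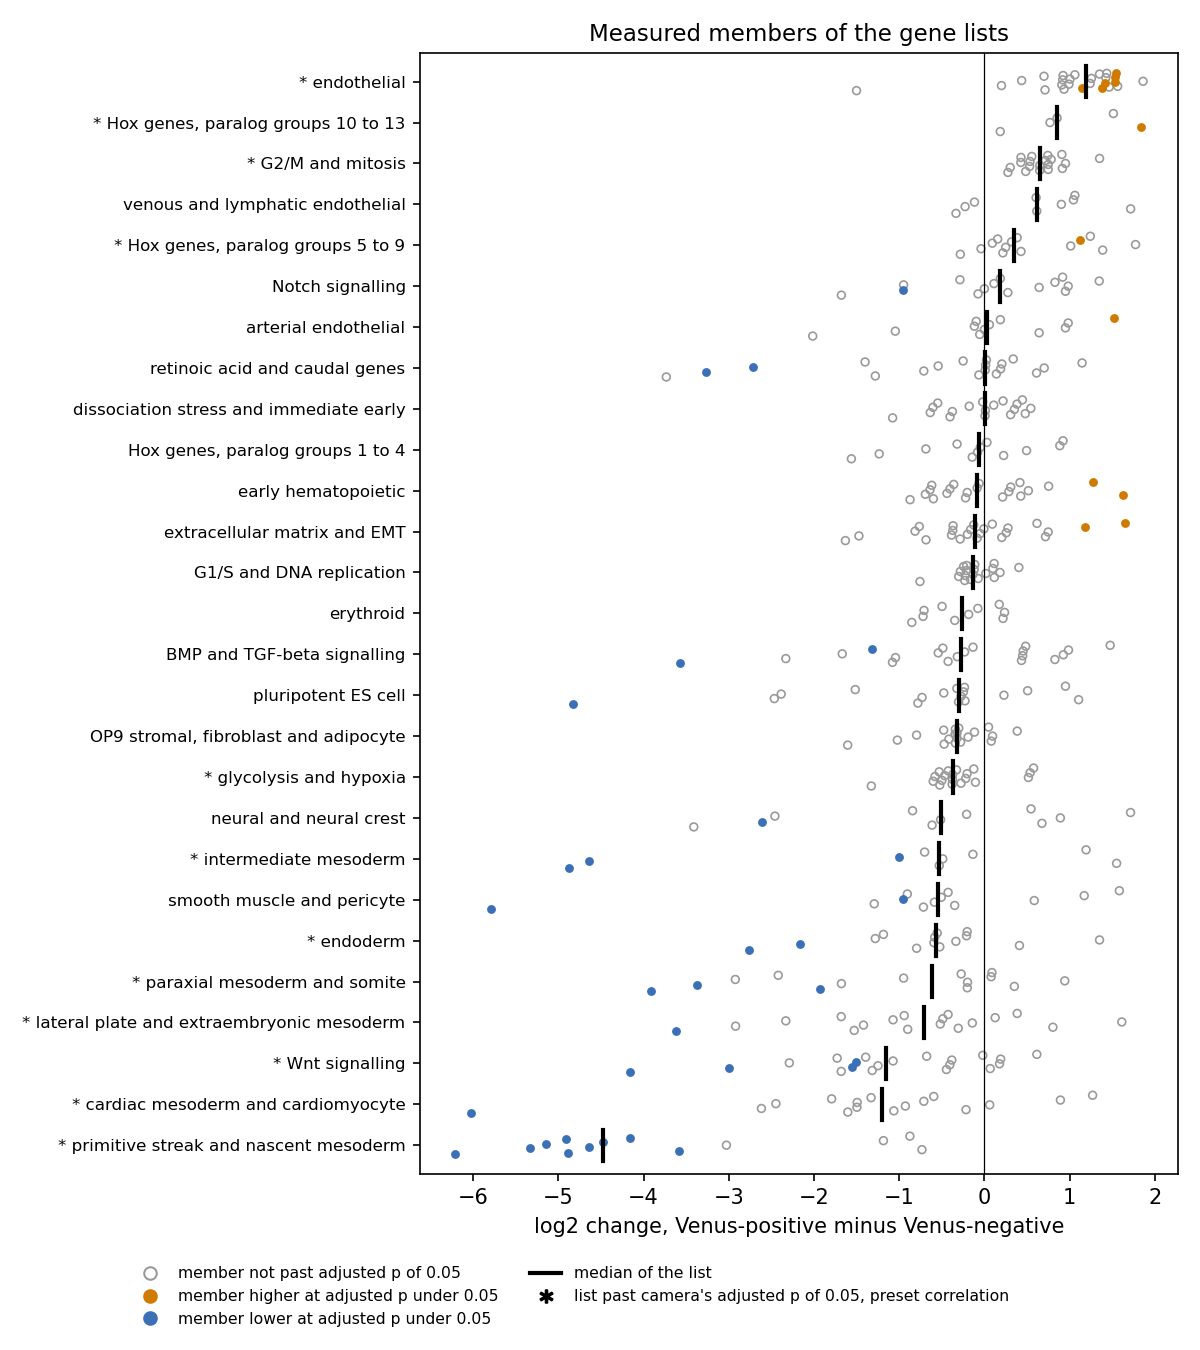
Log2 change (Venus-positive minus Venus-negative, horizontal axis) of each measured member of the 27 gene lists, 1 list per line; filled points are members past an adjusted p of 0.05 over all genes, black bars are list medians, and an asterisk marks lists past camera's threshold at the preset correlation. The primitive streak list has its median at -4.48 and the endothelial list at 1.20.

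The blood lists were not called. The 21 early hematopoietic genes had a median of -0.09 but a mean of 0.03 (adjusted p = 0.926), and a median of -0.13 without Venus-negative replicate 1, 0.16 without Venus-negative replicate 2, -0.15 without Venus-positive replicate 1 and -0.03 without Venus-positive replicate 2, with 2 genes higher both over all genes and adjusted over the list alone: Cd34, a surface antigen of endothelial and blood progenitors (3.09-fold, log2 change 1.63 ± 0.16), and Kit, the stem cell factor receptor (2.41-fold, 1.27 ± 0.11). The 10 erythroid genes had a median of -0.27 (adjusted p = 0.208). It was -0.56 without Venus-negative replicate 1 (adjusted p = 0.00456), -0.01 without Venus-negative replicate 2 (0.938), -0.24 without Venus-positive replicate 1 (0.387) and -0.49 without Venus-positive replicate 2 (0.217), with Klf1 at -0.85 ± 0.68 and Hbb-bh1 at -0.72 ± 0.46. The OP9 stromal, pluripotent, neural and smooth muscle lists did not pass with all 4 arrays in the reported fit. The 19 OP9 stromal, fibroblast and adipocyte genes had a median of -0.32 (adjusted p = 0.148), and of -0.14 without Venus-positive replicate 1, Thy1 standing at -1.60 ± 0.39 and Cxcl12 at -1.02 ± 0.60. The 17 pluripotent ES cell genes had a median of -0.30 (adjusted p = 0.148). Without Venus-negative replicate 2 the median was -1.04 and the adjusted p 0.00267, and the median was 0.06 without Venus-negative replicate 1, -0.73 without Venus-positive replicate 1 and -0.17 without Venus-positive replicate 2. In this list Lefty2 fell, and Dppa5a stood at -2.47 ± 0.40 (adjusted p = 0.0773). The 11 neural and neural crest genes had a median of -0.51 (adjusted p = 0.208, and 0.0426 in fry), which was -0.32 without Venus-negative replicate 2 and -0.33 without Venus-positive replicate 1. Tubb3, a neuronal tubulin, fell by 2.61 ± 0.27, and Otx2 stood at -3.41 ± 0.41 (adjusted p = 0.0551). The 12 smooth muscle and pericyte genes had a median of -0.55 (adjusted p = 0.0984, and 0.0233 with median centring). The median was -0.24 without Venus-negative replicate 1 (adjusted p = 0.250), -0.85 without Venus-negative replicate 2 (0.0284), -0.84 without Venus-positive replicate 1 (0.0271) and -0.27 without Venus-positive replicate 2 (0.217). Their 2 called members were Rgs5, a pericyte marker at least 12.5-fold lower (log2 change -1.78 with normexp), and Notch3 (-0.96 ± 0.10, named after the data were seen), and Mylk stood at 1.58 ± 0.35 (adjusted p = 0.117). Adjusted over each list alone, 0 erythroid and 0 OP9 stromal genes (in limma, at an unadjusted p under 0.05, 0 erythroid genes and 1 lower OP9 stromal gene), 3 lower pluripotent genes, 3 higher and 5 lower neural genes, and 3 higher and 5 lower smooth muscle genes were called.

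The remaining signalling and matrix lists held single large changes and were not called as lists. Bmp7, a bone morphogenetic protein, fell 11.9-fold (log2 change -3.57 ± 0.11), and 2 of 20 BMP and TGF-beta genes were lower, the other being Grem1 (-1.31 ± 0.12, named after the data were seen). The list's median was -0.28 (adjusted p = 0.127, and 0.0426 with median centring). It was -0.25 without Venus-negative replicate 1 (adjusted p = 0.250), -0.18 without Venus-negative replicate 2 (0.0640), -0.49 without Venus-positive replicate 1 (0.00646) and -0.11 without Venus-positive replicate 2 (0.862). Bmp5, measured on 1 of 2 Venus-positive arrays, stood at -2.33 ± 0.40. Aldh1a2, which makes retinoic acid, fell 9.61-fold (-3.26 ± 0.18), while Cyp26a1, which degrades retinoic acid, stood at -3.73 ± 0.70 (adjusted p = 0.0943). The 19 retinoic acid and caudal genes, of which 2 were lower over all genes, had a median of 0.01 but a mean of -0.56, and camera's direction was down (adjusted p = 0.148). With any 1 of the 4 arrays left out the median was negative, from -0.27 without Venus-positive replicate 1 (adjusted p = 0.00801) to -0.04 without Venus-positive replicate 2. Among 24 matrix and epithelial-mesenchymal transition genes, Nid1, a basement membrane protein, rose 3.13-fold (1.65 ± 0.15) on its representing probe. Other Nid1 probes gave 0.90 ± 0.31 (limma adjusted p = 0.203) and 1.96 ± 0.21 (0.0445). Zeb1, a transcription factor named after the data were seen, rose by 1.18 ± 0.12, and Snai1 stood at -1.63 ± 0.28 (adjusted p = 0.0846). The matrix median was -0.11 (adjusted p = 0.703), -0.05 without Venus-negative replicate 1 and -0.16 without Venus-negative replicate 2. Of 15 Notch signalling genes, Notch3 fell, Dll1 stood at -1.68 ± 0.23 and Mfng at 1.35 ± 0.42 (adjusted p = 0.0618 and 0.182), with a median of 0.19 (adjusted p = 0.623). The Notch median was 0.36 without Venus-negative replicate 1, 0.19 without Venus-negative replicate 2, -0.07 without Venus-positive replicate 1 and 0.62 without Venus-positive replicate 2. The 18 dissociation stress and immediate early genes had a median of 0.01 (0.03 without Venus-negative replicate 1, -0.04 without Venus-negative replicate 2, -0.10 without Venus-positive replicate 1 and 0.08 without Venus-positive replicate 2) but a mean of -0.05, and their adjusted p was 0.936, with Egr2 at -1.08 ± 0.36. Adjusted over each list alone, the higher and lower counts were 2 and 5 for BMP, 1 and 6 for retinoic acid, 3 and 4 for matrix, 1 and 2 for Notch, and 0 and 0 for stress genes, of which 3 were higher and 2 lower in limma at an unadjusted p under 0.05.

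The 10 largest increases among genes measured on all 4 arrays were in genes with varied known roles. Dnah6, an axonemal dynein heavy chain, rose 5.93-fold (log2 change 2.57 ± 0.22 SE), Crtac1, a matrix protein, 5.52-fold (2.47 ± 0.17), and Fbp1, a gluconeogenic phosphatase, 4.47-fold (2.16 ± 0.14). Slc1a2, a glutamate transporter, rose by 2.34 ± 0.15 on its representing probe, while a second probe gave 0.95 ± 1.21 (adjusted p = 0.679). With normexp the log2 change of Crtac1 moved to 1.30 and that of Slc1a2 to 1.12, and both genes still passed. Platr5, a noncoding transcript, Hecw2, a ubiquitin ligase, Cd109, a membrane-anchored protein, Tmem204, a membrane protein, Hapln1, a hyaluronan link protein, and Colgalt2, a collagen galactosyltransferase, had log2 changes of 2.10, 2.05, 2.01, 2.01, 1.90 and 1.88. Other Hecw2 probes gave 1.49 ± 0.24 (limma adjusted p = 0.0734) and 2.43 ± 0.10 (0.0286). Adjusted p-values of the 10 genes lay between 0.0342 and 0.0412. Among genes dim in the Venus-negative cells, Ctsg, a granule protease of myeloid cells, was at least 4.51-fold higher, Mansc1 at least 3.69-fold, Rd3 at least 2.43-fold and Txlnb at least 2.26-fold. With normexp, whose offset is large against such dim signals, smaller changes were built in, so the bounds are not tested by it. All 4 lay below these bounds there, with log2 changes of 0.59 (Ctsg), 0.47 (Mansc1), 0.39 (Rd3) and 0.28 (Txlnb). Ctsg alone passed (adjusted p = 0.0462, 0.103, 0.0847 and 0.204).

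Across the 27 lists, camera called 4 higher and 8 lower at the preset correlation, and 0 in either direction with a correlation estimated from 2 residual degrees of freedom. Among the called lists this estimate ran from -0.12 (Hox groups 10 to 13) to 0.836 (G2/M). Lists with an estimate below the preset 0.01 thus lost their call too. The alternative set test fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes, called 2 lists higher (endothelial, and venous and lymphatic) and 5 lower (streak, cardiac, paraxial, intermediate mesoderm and neural).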

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

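The tests of this part were chosen before the data were examined. The 394 called genes kept their sign in every setting in which they were tested. They had been chosen on these same arrays for changes large against their spread, so a reversal was unlikely and this is no separate support. Camera's direction reversed for 0 of the 4 higher and 8 lower lists, chosen on the same arrays too. The median of Hox groups 10 to 13 was nevertheless -0.07 with dim probes kept. Among lists past the threshold in neither fit camera's direction could turn, as for early hematopoietic and stress genes with the replicate block. Against 137 genes higher and 257 lower, normexp gave 491 and 538, median centring 259 and 296, the variance prior with trend 583 and 643, an adjusted p under 0.1 632 and 704, and an adjusted p under 0.01 gave 0 and 0 in limma, where 1968 and 1658 had an unadjusted p under 0.05. Without the filter on dim probes 0 and 0 genes passed (1736 and 1783 unadjusted), with 20658 in place of 13925 genes tested, and 3 lists were lower. Without 1 array the counts were 0 to 0 in both directions, with fewer samples in the fit and the lone array assumed to vary like the other group; unadjusted counts were 1344 and 1299 without Venus-negative replicate 1, 1514 and 1333 without Venus-negative replicate 2, 1116 and 1188 without Venus-positive replicate 1, and 1106 and 1111 without Venus-positive replicate 2. Of the 394 calls, 347 were kept with normexp, 382 with median centring, 383 with the trend and 393 with the deposited value table. Hoxb6 passed with normexp (0.98) and with the trend (1.01), where Kdr did too (0.44); without 1 array Hoxb6 ranged from 0.89 to 1.13 and Kdr from 0.35 to 0.52. With an estimated correlation camera called 0 lists higher and 0 lower, and fry 2 and 5. Hoxa11 ranged from -0.20 to 1.74 without 1 array: it reversed to -0.20 without Venus-negative replicate 1 and to -0.11 without Venus-positive replicate 2. Across 101 named genes and 14 settings, 1071 values stayed on their side of the threshold, 254 lost and 67 gained it. Except where fewer samples, more genes tested or another threshold set the count, the cause was not tested. Dim transcripts limit the folds, since 46 lower and 11 higher genes were at background in 1 fraction.

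The labels do not say that a replicate number marks a shared culture or day, although the row on the slide went with it. The deviations of same-numbered arrays from their group means correlated at 0.413 across genes, over only 2 pairs, and a replicate block gave 290 genes higher and 421 lower. With it the smooth muscle (adjusted p = 0.0225), OP9 stromal (0.00586) and pluripotent (0.0478) lists passed as lower.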

Other observations

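The tests on ES cells, on cells with little Flk-1, on dilution and on other splits of the arrays were chosen only after the result was seen, as were the genes named in the next 2 paragraphs. Single genes known from Nodal signalling, for which no list was fixed or tested, had the following values in the Venus-positive against the Venus-negative cells. Foxh1, a transcription factor that acts with Nodal signals, fell by 2.51 ± 0.11 SE on the log2 scale (limma adjusted p = 0.0342), and Gdf1, a ligand that pairs with Nodal, by 1.90 ± 0.12 (adjusted p = 0.0342). Nodal, a member of the streak list, fell by 3.59 ± 0.32 (adjusted p = 0.0395). The receptor genes Acvr1b and Acvr2b stood at 0.19 and -0.56 (adjusted p = 0.561 and 0.172), and Lefty1, of the pluripotent list, at -1.52 (adjusted p = 0.230). Among receptors of sphingosine phosphate, a lipid that acts on vessels, also not tested as a group, S1pr1 rose by 1.15 ± 0.10 (adjusted p = 0.0381), S1pr2 fell by 1.44 ± 0.10 (adjusted p = 0.0349), S1pr5 was at least 15.3-fold lower, and S1pr3 stood at -0.97 ± 0.13 (adjusted p = 0.0611).

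Of 222 gene families defined by the stem of the symbol with at least 8 measured members, 4 passed camera at an adjusted p under 0.05 at the preset correlation. With an estimated correlation 0 passed (adjusted p = 0.936), but that test rests on 2 residual degrees of freedom, so the loss decides nothing. A shift that members of a family share by chance on so few arrays was not tested and cannot be told apart from an effect of the fraction. Members such as Wnt3 and Wnt5a are also in the Wnt list, so the family result is not independent of it. The Wnt family had 13 members with 0 positive log2 changes, a median of -1.51 (adjusted p = 1.54e-06) and 4 genes lower: Wnt3, Wnt5a, Wnt10a (-1.89 ± 0.12, adjusted p = 0.0342) and Wnt9b, at least 5.82-fold lower on the processed signal (adjusted p = 0.0349). The Fgf and Rrp families had medians of -0.48 and -0.40 and the Tbc family 0.23, each with an adjusted p of 0.0333, and the signs of these 4 medians were the same with quantile normalization, median centring and normexp, although normexp moved the Wnt median to -0.73. Among 4670 unnamed probes with a position, 25 were higher and 17 lower. In build mm9, a probe for chromosome 1, 63264155 to 63345773, was 25.1-fold higher in Venus-positive cells (log2 change 4.65 ± 0.22, adjusted p = 0.0342), and one for chromosome 3, 19179899 to 19216399, was 6.54-fold higher (2.71 ± 0.11, adjusted p = 0.0278).

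The streak genes were lower by a median of 4.48 on the log2 scale in Venus-positive cells. A trend with signal strength is argued against, since the list's median lay at percentile 0 of 10000 random lists matched on mean signal, whose medians ranged from -0.73 to 0.73. Undifferentiated ES cells in the Venus-negative fraction would carry pluripotency transcripts along, but the 25th percentile of 15 such genes without Lefty1 and Lefty2 was -0.60, and -1.37 at its lowest, without Venus-negative replicate 2. Their median ran from 0.14 without Venus-negative replicate 1 to -0.985 without Venus-negative replicate 2. A small share of such cells is not excluded by these values. Cells with little Flk-1 inside the Venus-negative gate cannot be told apart from a real difference: Kdr differed by 0.44, a small share of such cells would hardly move it, and other endothelial genes moved the same way. An earlier mesodermal state of the Venus-negative Flk-1+ cells stays open as a hypothesis that was not tested.

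Endothelial genes were higher by a median of 1.20. Their median lay at percentile 100 of matched random lists, whose highest was 0.31, which argues against a trend with signal strength. If the Flk-1+ cells of the Venus-negative fraction had been diluted by cells without blood transcripts, blood genes would be higher as well, by about the same amount. This assumes that undiluted Flk-1+ cells of both fractions carry equal levels of blood transcripts, which was not tested. The 75th percentile of 31 blood genes outside the endothelial lists was 0.26 and their median -0.19. Without Venus-negative replicate 2 these were 0.61 and 0.15, against an endothelial median of 1.37. Between the 2 Venus-negative arrays the early hematopoietic list differed by a median of 0.51 and the erythroid list by 1.00, with replicate 2 the higher. The comparison cannot decide on dilution by cells that carry blood transcripts themselves, or on dilution masked by unequal blood transcripts of the fractions. A larger endothelial share or a later state of the Venus-positive cells may account for the difference and was not tested.

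The mitotic list had a median of 0.65 but 0 members called in limma, and camera's call was lost with an estimated correlation (adjusted p = 0.538) and in fry (0.164). The median lay at percentile 100 of matched random lists (highest 0.37), which argues against a trend with signal strength. Spread between replicate cultures or libraries cannot be told apart from an effect of the fraction, since the list differed by 0.49 between the 2 Venus-negative arrays, with replicate 2 the lower, and by -0.09 between the 2 Venus-positive arrays (replicate 2 minus replicate 1). A difference in proliferation stays open and was not tested. For the count of called genes, the real split of the 4 arrays gave 394 in limma (3626 at an unadjusted p under 0.05) and the highest of the other splits 0 (652 and 36 unadjusted). In the other splits each group held 1 array of each fraction, so the difference between fractions entered their spread. Their low counts are therefore no measure of what arises without a difference. With 1 of 3 splits reaching the real count, the splits are also too few for a share under 0.05.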
